A study of Homo sapiens with 20 samples.

How the data were processed

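The series comprised 20 Agilent one-colour arrays, each hybridized with Cy3-labelled RNA of 1 xenograft. Per the labels, frozen leukaemia cells were injected into NOD/SCID mice, spleen cells were collected once the mice were ill, total RNA was extracted with Trizol, and the cells used for RNA were untreated. RNA was amplified and labelled with a low-input Agilent kit, per the labels. Per the file headers, the images were read with Agilent Feature Extraction 10.7.1.1. The deposited processed signal is an intensity, per the file headers: spot brightness after background subtraction and detrending within the array, on a linear scale, not normalized between arrays. The deposited median spot and background columns are also intensities, with no correction. The flag columns deposited with them hold 0 or 1. The submitters' processing notes name limma without a version or a role.

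Groups followed the stated response to GANT-61 in the labels: 6 sensitive, 10 resistant and 4 with none stated, which were reported only as values. Replicate numbers follow the order of the records and carry no meaning. The labels do not say how sensitivity was scored or which threshold divided the groups. Slide and scanning session were read from the files.

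Each array held 62976 spots, of which 58717 were not controls. Spots marked by the extraction software as non-uniform or as outliers among replicate spots were set aside, and the rest were averaged on the log2 scale to 42405 probes. Probes were named by matching the accession in the files to a table of RefSeq genes: 26364 probes had 1 symbol, covering 19796 symbols, and 16041 had none and kept the identifier of the files. For reasons of donor privacy, 153 probes were left out of all tables. Log2 signals were set relative to each array's 75th percentile over non-control probes. A gene was represented by its probe with the highest mean over the 16 arrays, giving 34322 genes, and 25042 were kept whose probe was well above background on at least 6 of the 16, 15112 of them with a symbol. Of 400672 values, 254 were missing.

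Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, sensitive minus resistant), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were compared with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists. List scores were means of z-values over the measured members, compared by exact two-sided permutation over all 8008 splits of 16 arrays into 6 and 10, and over the 180 splits that keep each slide's numbers. Distance between groups was tested with the pseudo-F of Euclidean distances, one-sided. Correlations were tested with 100000 two-sided permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the other steps. All p-values but those of camera at the preset correlation measure the spread between xenografts. Camera at that setting compares the members of a list with other genes and treats the members as nearly independent.

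The 31 lists, written from general knowledge before the data were examined, covered Hedgehog pathway components, GLI target genes, glucocorticoid-induced genes, the glucocorticoid receptor complex, the NOTCH pathway and its targets, MYC targets, immature and stem cell genes, T-ALL oncogenes, HOXA and MEIS genes, cortical thymocyte genes, the T cell receptor complex, T lineage transcription factors, the WNT pathway, cell cycle, the BCL2 family, p53 targets, PI3K and mTOR signalling, JAK-STAT signalling, NF-kB targets, interferon response, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, drug transporters, and immediate early and heat shock genes. The other 6 held markers of erythroid, B, myeloid, natural killer, megakaryocyte and stromal cells. Of 509 genes listed, 439 could be tested.

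Genes were named by a rule set at the same time: in each direction the 12 with the smallest p among those with a difference of at least 1 log2 unit and a gene symbol, then GLI1, GLI2, GLI3, PTCH1, SMO, SUFU and NR3C1, and in each list the 2 measured members with the smallest p. A few genes that the rule named are not reported here one by one, though they stayed in the fits and the list statistics, which left 88 genes. Further list members given as examples, and FLJ12825, were chosen after their values were seen.

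Alternatives set before the data were examined were quantile normalization, normexp background correction (offset 50) followed by quantile normalization, median centring, no filter, a filter asking for all 16 arrays, the mean of all probes of a gene, every probe on its own (30462 probes), slide as a fixed or random block, trended robust moderation, array weights, a threshold of 0.1, camera with an estimated correlation, fry, scores from log2 values, all 20 arrays for the correlation, and leaving out each xenograft in turn. The files lack a column of mean spot brightness, so normexp used the median. Alternatives added later were named genes only, arrays without the 2 dimmest, arrays without those and the 1 marked for evaluation, and array brightness as a covariate.

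The fit was tested on simulated data with the real mean and pooled within-group spread of each gene, over 10 runs. Noise was normal and independent between genes, and genes of every size of shift were changed in the same run. The fit recovered 27.6% of genes shifted by 1 log2 unit, 69.6% of those shifted by 2, 87% by 3 and 94.8% by 4, out of 500 each, and 4.58% of its calls were false. On the real arrays genes vary together and the groups can differ in spread, so these rates may not carry over. Depth on these arrays is the share of probes well above background, between 61.6% and 89.6% on the 16 arrays.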

Results

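The series measured gene expression in 20 xenografts of human T-cell acute lymphoblastic leukaemia (T-ALL), a cancer of immature T-lineage cells, grown in NOD/SCID mice, a strain whose lack of lymphocytes lets human cells grow. RNA came from the spleen cells of mice with overt disease and had received no treatment. Cells of the same leukaemias had been exposed in culture to GANT-61, a small molecule that blocks GLI1 and GLI2, the transcription factors at the end of the Hedgehog pathway. By their stated response, 6 xenografts were sensitive and 10 were resistant, with 1 array each. A further 4 had no stated response and entered no comparison. The question put to the arrays was whether expression before treatment differed between sensitive and resistant leukaemias, first in the pathway that the drug blocks. No 2 of the 20 arrays held identical values. The xenograft was the replicate, each taken as independent, and whether any of them share a donor was not examined. The number of arrays limited the precision: the median 95% confidence interval of a gene's difference reached 0.70 log2 units to either side.

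No difference in array quality between the groups was detected. The share of probes well above background was 68.1% ± 4.46 (SD, n = 6) in sensitive and 69.3% ± 8.28 (SD, n = 10) in resistant xenografts, with an exact two-sided permutation p of 0.776 over 8008 splits. The 75th percentile of log2 signal was 8.60 ± 0.29 (SD, n = 6) against 8.71 ± 0.68 (SD, n = 10), with an exact p of 0.722, and the median background brightness of 23.7 against 23.8 units gave an exact p of 1.0. The arrays lay on 4 slides. Slide 1 held 2 sensitive and 4 resistant xenografts, slide 2 held 1 and 5, slide 3 held 2 sensitive ones only, and slide 4, scanned in a session of its own, held 1 of each. No association of slide and group was detected (chi-square 4.62, exact permutation p = 0.418), but so few arrays cannot exclude one. The 2 sensitive xenografts of slide 3 had no resistant ones beside them, so they entered no within-slide difference. Resistant replicate 5, the array that the extraction software marked for evaluation, stood apart with 89.6% of probes well above background. Resistant replicates 8 and 1 were the dimmest arrays, with 75th percentiles of 7.28 and 7.90.

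**Figure D1:**
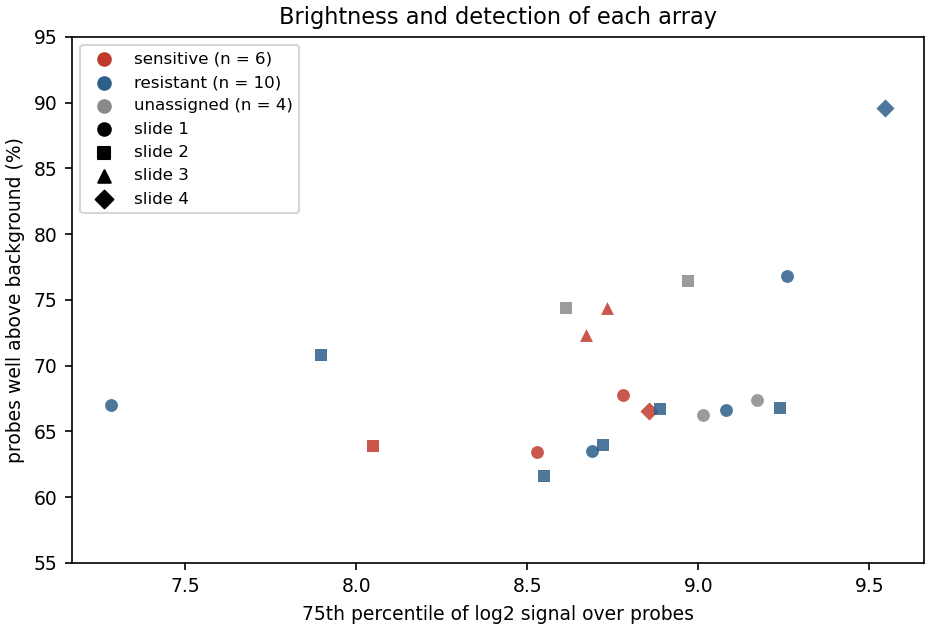
Each point is 1 array, with its 75th percentile of log2 signal over probes on the horizontal axis and the percentage of probes well above background on the vertical axis, coloured by stated response and shaped by slide. Resistant replicate 5, at 89.6% on slide 4, lies above every other array, and resistant replicate 8 is the dimmest at 7.28.

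Taken gene by gene, no difference between xenografts that responded to GANT-61 and those that did not passed the threshold. Of 25042 genes tested with limma, 0 passed an adjusted p of 0.05, and 767 had an unadjusted p under 0.05, which is 3.06% of those tested. Of the 767, 414 were higher and 353 lower in sensitive xenografts. With each array centred on its median the numbers were 425 and 205, because that scaling moved the median difference of all genes from -0.03 to 0.12. The majority turned with slide as a fixed block, at 358 higher and 532 lower, and with no filter, at 403 and 452. The smallest adjusted p over all genes was 0.26. The values of the 24 leading genes are therefore given as measured, with no claim that they differed.

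Among genes with higher values in sensitive xenografts, the first was SEPTIN11, a cytoskeletal GTPase (probe A_33_P3310475). Its log2 level, relative to each array's 75th percentile, was 2.40 ± 0.56 (SD, n = 6) in sensitive and -0.41 ± 1.27 (SD, n = 10) in resistant xenografts, a difference of 2.81 (95% confidence interval 1.70 to 3.91) with an adjusted p of 0.342. Its groups did not overlap, and the difference was 2.94 within slide 1, 3.01 within slide 2 and 2.77 within slide 4. The sialyltransferase gene ST3GAL1 followed at 1.33, then ZFPM2, a cofactor of GATA factors, at 3.63, and the hepatic lipase gene LIPC at 1.46. ZFPM2 was well above background on 5 of 6 sensitive arrays and 1 of 10 resistant ones. Among the other 8, UBASH3B, a phosphatase that dampens T cell receptor signals, differed by 1.06, the prostaglandin E2 receptor gene PTGER2 by 2.05, and the ubiquitin ligase gene RNF125 by 1.098. MYO1F, an unconventional myosin, differed by 1.97, the calcium-binding SRI by 1.32, PGBD4 by 1.40, the protease inhibitor gene CST7 by 3.14, and the zinc finger gene ZNF114 by 2.62. CST7 was well above background on 6 sensitive and 3 resistant arrays, and ZNF114 on 5 and 2. After normexp and quantile normalization ZFPM2 differed by 1.60, CST7 by 1.5 and ZNF114 by 0.75, and within slide 4, which held 1 xenograft of each group, 5 of these genes had the opposite sign: MYO1F at -0.35, SRI at -0.18, RNF125 at -0.65, CST7 at -1.31 and ZNF114 at -2.82. Apart from SEPTIN11, the adjusted p of each of these genes was 0.9998.

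Among genes with lower values in sensitive xenografts, the RNA-binding protein gene RAVER2 came first. Its difference was -3.14 (95% confidence interval -4.28 to -2.01) with an adjusted p of 0.26, all 6 sensitive xenografts lay below the resistant mean, and its probe was well above background on 2 of 6 sensitive and all 10 resistant arrays. Within slides 1, 2 and 4 the difference was -3.77, -1.40 and -0.79, and -2.47 with slide as a block. After normexp and quantile normalization the difference was -0.91. METRN, which encodes the secreted protein meteorin, stood at 2.81 ± 0.85 (SD, n = 6) against 4.79 ± 0.61 (SD, n = 10), a difference of -1.98 with an adjusted p of 0.281. Its groups did not overlap, and its within-slide differences were -1.38, -3.09 and -0.98. Of all 25042 genes, 4 had groups without overlap, where chance alone gives 0.025% of genes, or 6.25. LEF1-AS1, an RNA antisense to the T-lineage factor gene LEF1, differed by -1.49, the cell cycle transcription factor gene E2F5 by -1.18 and the tyrosine phosphatase gene PTPN3 by -2.47. ZNF618 differed by -4.29, NBEA by -1.92, ANTKMT by -1.63, REG4 by -2.61, RAB6D by -1.87, and the long non-coding RNAs LINC01777 and LINC00239 by -3.31 and -2.26. Their adjusted p was 0.9998 in each case. After normexp and quantile normalization RAB6D differed by -0.73, LINC01777 by -1.64, REG4 by -1.19, ZNF618 by -2.61, NBEA by -1.17 and LINC00239 by -0.87, and REG4 differed by -1.41 with the mean of its probes. Within slide 2 NBEA differed by 0.05, the opposite sign. A call arose in 2 of the fits that left out 1 xenograft: RAVER2 passed without sensitive replicate 6 (-3.61, adjusted p = 0.0267), and FLJ12825, named here after its values were seen, passed without sensitive replicate 3 (-2.02, adjusted p = 0.023).

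No difference was called in the pathway that GANT-61 blocks, though the confidence intervals of several of its genes leave room for differences of over 1 log2 unit. Of 20 listed components of the Hedgehog pathway, 17 could be tested, and 0 passed, whether adjusted over all genes or adjusted over the list alone. GLI1, a target of the drug and of the pathway itself, was a dim transcript in most xenografts: its log2 level was -1.89 ± 1.09 (SD, n = 6) in sensitive and -2.83 ± 1.14 (SD, n = 10) in resistant ones, a difference of 0.95 (95% confidence interval -0.20 to 2.09). Resistant replicate 10 stood at 0.23, against -3.70 to -2.41 in the other resistant xenografts. The GLI1 difference was 1.29 without that xenograft and 0.71 without sensitive replicate 2, and 0.58 at its smallest over all settings tried. GLI2, the other target of the drug, differed by -0.24 (-0.91 to 0.42) and was well above background on 4 of 6 sensitive and 8 of 10 resistant arrays. GLI3, the mostly repressing member of the family, differed by 0.99 with a confidence interval from -1.49 to 3.47, and was well above background on 5 arrays of each group. Leaving out 1 xenograft moved GLI3 to between 0.48 (without sensitive replicate 3) and 1.88 (without sensitive replicate 1).

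The receptor gene PTCH1, itself a Hedgehog target, differed by -0.44 (95% confidence interval -1.68 to 0.81). SMO, the signal transducer upstream of the GLI proteins, differed by 0.45, with a confidence interval of -1.21 to 2.11. PTCH1 was 0.01 without sensitive replicate 2 and -0.74 without sensitive replicate 4, and SMO was -0.13 without resistant replicate 10 and 0.82 without sensitive replicate 1. SUFU, which holds GLI proteins inactive, differed by -0.15, and other probes of SUFU gave the opposite sign. HHIP, which binds Hedgehog ligands and is induced by the pathway, was the member with the smallest p: 2.63 ± 0.57 (SD, n = 6) against 1.85 ± 0.43 (SD, n = 10), higher than the resistant mean in 6 of 6 sensitive xenografts, with an adjusted p of 0.9998 over all genes and 0.137 adjusted over the list alone. Within slides 1, 2 and 4 GLI1 differed by 0.93, 1.89 and -1.08, and it differed by 0.85 with slide as a block. The blocked differences of the others were -0.46 for GLI2, 0.15 for GLI3, -1.38 for PTCH1, 0.28 for SMO, -0.59 for SUFU and 0.87 for HHIP. Within those slides PTCH1 differed by -1.77, -1.80 and 0.38, and GLI3 by -2.23, 2.03 and 3.34.

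As a set, the 17 components held 6 with positive and 11 with negative differences. Their median difference was -0.12 and their mean 0.03, while limma's camera, which compares a list with all other genes, pointed up with an adjusted p of 0.987. The score made of their z-values differed by -0.0211 (exact two-sided permutation p = 0.912, and 0.933 when labels were permuted within slides). Within slides 1, 2 and 4 that score differed by -0.429, 0.277 and -0.454. Among 14 measured GLI target genes, 7 were positive and 7 negative, camera gave an adjusted p of 0.26, and the score differed by 0.175 (exact p = 0.246, and 0.691 after adjustment over the 31 lists). The members nearest to the threshold were HHIP and the cyclin gene CCNE1, at 0.77 and 0.85, each with 0.0781 adjusted over the list alone. Of the 14 genes, 4 were also in the list of components.

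**Figure D2:**
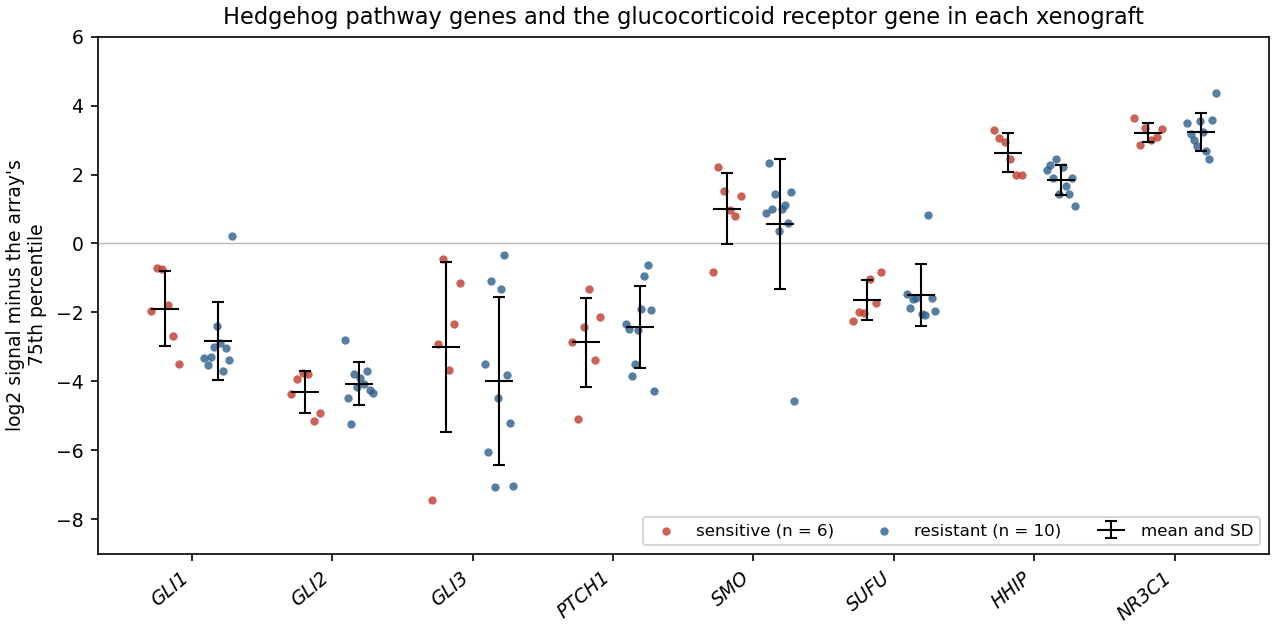
Each point is 1 xenograft, with the gene on the horizontal axis and log2 signal minus the array's 75th percentile on the vertical axis, and bars for the mean and SD of 6 sensitive and 10 resistant xenografts (9 for SUFU, with 1 value missing). The groups overlap in all 8 genes, and resistant replicate 10 lies apart from its group with GLI1 at 0.23 and SMO at -4.59.

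No difference was called for the glucocorticoid receptor gene either. It was examined because the study behind the series, as far as known, dealt with Hedgehog and glucocorticoid receptor signalling. Glucocorticoids, which kill lymphoid cells through this receptor, are a mainstay of T-ALL treatment. NR3C1, the gene of the receptor, was bright in both groups, at 3.22 ± 0.28 (SD, n = 6) in sensitive and 3.24 ± 0.54 (SD, n = 10) in resistant xenografts, a difference of -0.02 (95% confidence interval -0.55 to 0.50). Within slides 1, 2 and 4 it differed by 0.37, -0.51 and -0.22, and by -0.01 with slide as a block. Of 20 glucocorticoid-induced genes, 0 passed over all genes and 1 passed adjusted over the list alone: ISG20, an exonuclease gene, at 0.73 (95% confidence interval 0.30 to 1.16, 0.0449 adjusted over the list alone, above the resistant mean in 6 of 6 sensitive xenografts). The interleukin 7 receptor gene IL7R differed by -2.33 and BCL2L11, which encodes the death-promoting BIM, by -0.61 (-0.39 without sensitive replicate 2), and neither passed. Other probes of BCL2L11, well above background on all 16 arrays, differed by only -0.12 and -0.16. Camera gave that list an adjusted p of 0.987. The receptor's chaperones and cofactors, 16 genes, had a median difference of -0.10 and an adjusted p of 0.26, with FKBP4 at -0.47 (-0.28 without resistant replicate 8) and NCOA1 at -0.27.

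GLI1 and NR3C1 levels were not clearly related across the 16 xenografts (Pearson r = 0.455, permutation p = 0.0792, and Spearman rho = 0.268, permutation p = 0.315, or 0.144 and 0.315 after Benjamini-Hochberg adjustment over the 2 relations computed). Without the 2 xenografts farthest from the median of GLI1, r was 0.261. The pooled value rested on resistant replicate 10, without which r was 0.0832. It passed an unadjusted p of 0.05 without sensitive replicate 2 (r = 0.605, permutation p = 0.021) and without resistant replicate 9 (r = 0.519, permutation p = 0.0498). Within slides 1 and 2, of 6 arrays each, r was 0.487 and 0.549. The other slides held too few arrays. Within the 10 resistant xenografts r was 0.735 (permutation p = 0.0265, and 0.053 adjusted over 4 relations within groups), falling to -0.102 without the 2 farthest. Within the 6 sensitive ones it was -0.25 (exact permutation p = 0.608).

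Genes of the NOTCH pathway had the largest median shift of the 31 lists. NOTCH1 signalling drives many T-ALLs, and the list holds receptors, cofactors and direct targets. Of 16 measured members, 15 had lower mean values in sensitive xenografts. The median difference of the 16 was -1.70, and between -2.42 and -0.47 over all settings tried. The list stood below the other genes (camera adjusted p = 1.14e-07). The call was lost when the correlation between members was taken from the data (adjusted p = 0.221 with an estimated correlation). The test fry, which asks whether the members move one way and not how they stand against other genes, gave an adjusted p of 0.44. No member passed over all genes, and 2 passed adjusted over the list alone. These were HES4, a transcriptional repressor and NOTCH target, at 0.72 ± 6.26 (SD, n = 6) against 7.47 ± 1.60 (SD, n = 10), and the receptor gene NOTCH3 at -0.01 ± 4.07 (SD, n = 6) against 4.10 ± 1.38 (SD, n = 10), with values of 0.0377 and 0.0401 adjusted over the list alone. The adjustment over the list alone does not allow for the 31 lists tried. The spread within the sensitive group was wide, and 4 of 6 sensitive xenografts lay below the resistant mean of each gene.

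Other targets of NOTCH differed in the same direction without passing: the pre-T-cell receptor gene PTCRA by -3.27, HES5 by -3.27, the ubiquitin ligase gene DTX1 by -4.37, CR2 by -4.01 and HES1 by -2.19. HES5, DTX1 and HES1 were well above background on 2 of 6 sensitive arrays and CR2 on 4, so the sizes of these differences are uncertain. Several members were closer to 0, among them NOTCH1 at -0.24, the target HEYL at -0.21, the DNA-binding partner RBPJ at -0.03 and the coactivator MAML1 at -0.08, and FBXW7, which degrades the active receptor, was the 1 positive member at 0.31. The list's score was -0.401 ± 0.556 (SD, n = 6) in sensitive and 0.241 ± 0.38 (SD, n = 10) in resistant xenografts. It lay below every resistant xenograft in 4 of 6 sensitive ones and above the resistant mean in the other 2. The difference of -0.642 had an exact permutation p of 0.0177, or 0.0389 within slides, and 0.55 after adjustment over 31 lists. The list median was -1.46 with slide as a block, and -0.29, -3.61 and -0.71 within slides 1, 2 and 4. These values did not draw on sensitive replicates 3 and 4 of slide 3, which were among the 4 below every resistant xenograft. The NOTCH list score difference had an exact p of 0.0539 without sensitive replicate 2, 0.0845 with median centring and 0.0559 over the members well above background on all 16 arrays. Within slides 1, 2 and 4 HES4 differed by -5.65, -11.91 and -0.59, and NOTCH3 by -2.59, -7.20 and -0.82.

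**Figure D3:**
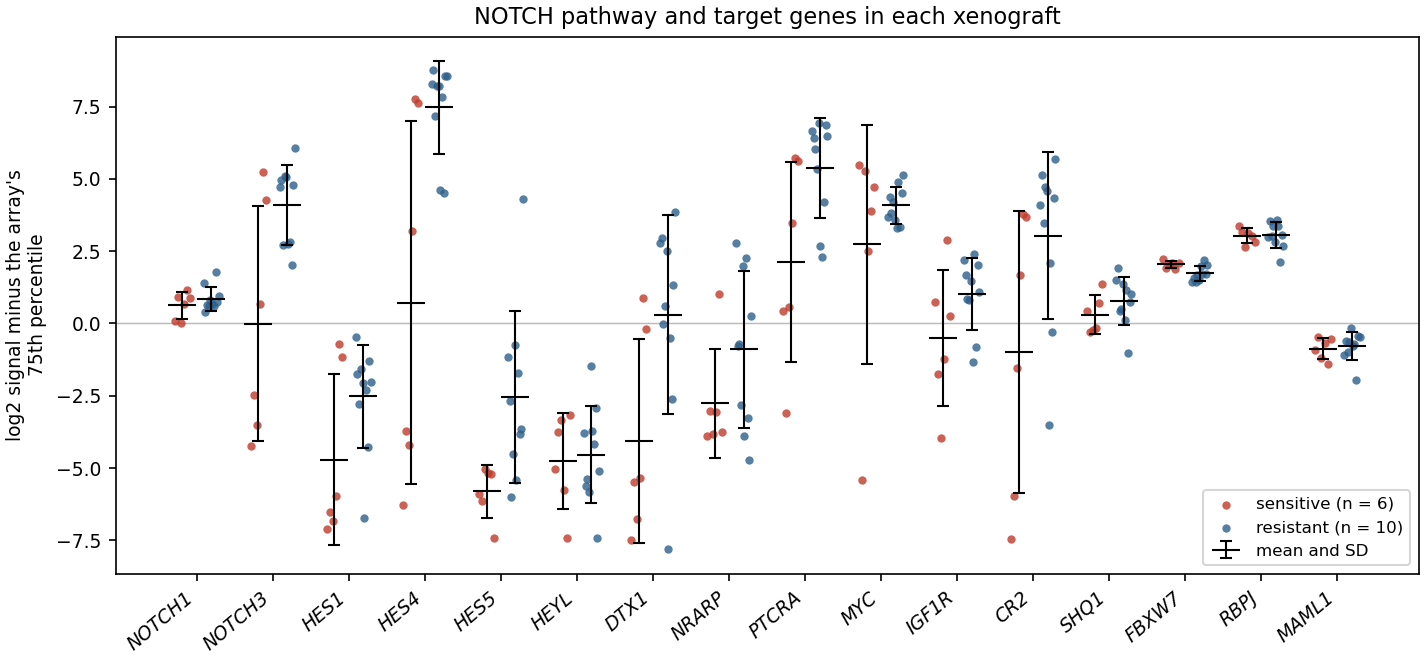
Each point is 1 xenograft, with the 16 measured genes of the NOTCH list on the horizontal axis and log2 signal minus the array's 75th percentile on the vertical axis, and bars for the mean and SD of 6 sensitive and 10 resistant xenografts. For HES4 and NOTCH3, 4 of 6 sensitive xenografts lie below the resistant mean and the other 2 lie among the resistant ones.

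Genes of the cortical thymocyte, the stage of T cell development at which many T-ALLs are arrested, also stood lower as a list by camera. Of 14 measured members, 11 were negative, with a median of -0.52 and a camera adjusted p of 0.00475 (adjusted p = 0.532 with an estimated correlation). The list's score differed by -0.424 (exact permutation p = 0.201, or 0.111 within slides, and 0.691 after adjustment over all lists). CD1E and CD1B, lipid-presenting molecules of that stage, differed by -2.34 and -2.47, the recombinase gene RAG1 by -1.80 and DNTT by -0.60. CD1E was at -1.04 without sensitive replicate 2. The other CD1 genes were nearer to 0 or higher, with CD1A at -0.26, CD1D at -0.27 and CD1C at 0.56. PTCRA is on this list too. CD4 was at -0.18, CD8A at 0.07 and CD8B at -0.82, and 0 members passed under either adjustment. The call ended without sensitive replicate 2 (median -0.17, adjusted p = 0.228) and without resistant replicate 10 (median -0.42, adjusted p = 0.0904). Within slides 1, 2 and 4 the median was 0.45, -3.48 and -0.38, so slide 1 went the other way, and it was -0.94 with slide as a block.

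Immediate early and heat shock genes, which respond within minutes to growth signals or to handling of cells, made the third list that stood lower by camera. Of 18 members, 16 were negative, with a median of -0.38 and a camera adjusted p of 8.74e-04 (adjusted p = 0.475 with an estimated correlation). The list's score differed by -0.447 (exact permutation p = 0.0656, or 0.05 within slides, and 0.566 after adjustment over all lists). EGR1, an early growth response factor, differed by -1.13, and the heat shock genes HSPA1A and HSPA1B by -1.61 and -1.45. ATF3 and DUSP1 were positive at 0.22 and 0.30, and 0 members passed under either adjustment. The medians within slides 1, 2 and 4 were -0.64, -0.36 and -0.49. With slide as a block the median was -0.76.

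Genes of energy metabolism stood higher than other genes by camera, by small amounts, but their list scores did not pass after adjustment. For oxidative phosphorylation, the mitochondrial production of ATP, 20 of 21 members were positive with a median of 0.19 and a camera adjusted p of 4.43e-06 (adjusted p = 0.478 with an estimated correlation). The list's score differed by 0.631 (exact permutation p = 0.054, or 0.0389 within slides, and 0.566 after adjustment over all lists). SDHA and COX5A, subunits of respiratory complexes, differed by 0.38 and 0.39, and UQCRC2 by 0.48, with 0 members passing under either adjustment. The median was 0.34, 0.02 and 0.32 within slides 1, 2 and 4, and 0.25 with slide as a block. The list lost its call under quantile normalization (median 0.10, adjusted p = 0.054) and on leaving out the 2 dimmest arrays together with resistant replicate 5 (median 0.08, adjusted p = 0.288).

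For glycolysis and hypoxia, 12 of 17 members were positive, with a median of 0.28 and an adjusted p of 0.0384 (adjusted p = 0.475 with an estimated correlation). The list's score differed by 0.322 (exact permutation p = 0.073, or 0.156 within slides, and 0.566 after adjustment over all lists). The median was 0.10, -0.12 and 0.11 within slides 1, 2 and 4, so slide 2 went the other way, and 0.11 with slide as a block. The glucose transporter gene SLC2A1 differed by 0.41 and the hexokinase gene HK2 by 1.86, whereas the hypoxia-induced ADM differed by -1.02. For NF-kB target genes, 12 of 15 were positive, with a median of 0.34 and an adjusted p of 0.0423 (adjusted p = 0.532 with an estimated correlation). Their median was 0.08, 0.24 and 0.08 within slides 1, 2 and 4, and 0.19 with slide as a block. The NF-kB score differed by 0.316 (exact permutation p = 0.195, or 0.283 within slides, and 0.691 after adjustment over all lists). CD83, an activation marker, differed by 1.28 and NFKBIE by 0.46, whereas TNF and IER3 differed by -2.07 and -1.31. Neither list had a member that passed, and both lost the call with slide as a block (adjusted p = 0.249 and 0.294) and without the 2 dimmest arrays (adjusted p = 0.362 for both).

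**Figure D4:**
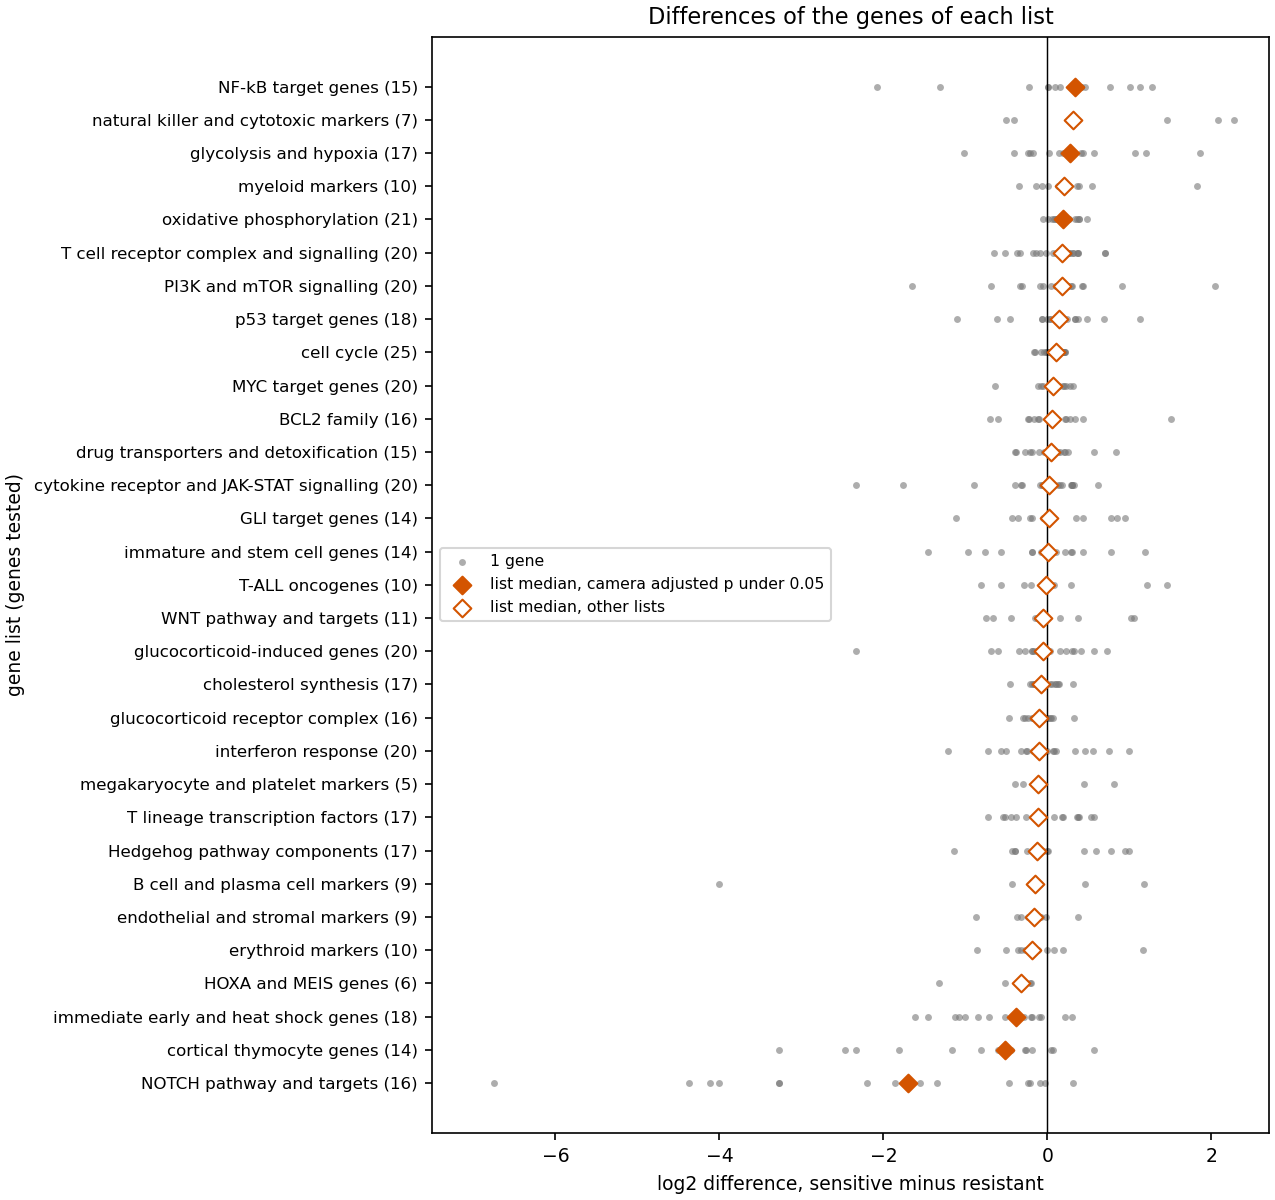
Each row is 1 of the 31 gene lists, each grey point the log2 difference of 1 gene, sensitive minus resistant, and each diamond the list's median, filled where camera gave an adjusted p under 0.05. The NOTCH list lies farthest from 0, with a median of -1.70, and the 6 filled lists are 3 lower and 3 higher ones.

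The other 25 lists gave camera adjusted p-values between 0.113 and 0.987. In the genes of T cell identity, the T cell receptor complex list had 12 of 20 members positive (adjusted p = 0.128), with UBASH3A at 0.71 and the receptor chain gene CD247 at -0.51. T lineage transcription factors had 8 of 17 positive (adjusted p = 0.831). Among them BCL11B, a factor that fixes T cell fate, was at -0.44, and at -0.07 by its other probe. The WNT list had 4 of 11 positive (adjusted p = 0.831), with AXIN2 at -0.67. Of T-ALL oncogenes, 4 of 10 were positive (adjusted p = 0.831), with TAL1 at 1.46 (0.72 without resistant replicate 10) and TAL2 at -0.80 (-0.20 at its nearest to 0 over all settings tried). All 6 measured HOXA and MEIS genes were negative (adjusted p = 0.128), with HOXA7 at -1.33 (-0.64 without resistant replicate 10 and -2.0 without sensitive replicate 2). Immature and stem cell genes split evenly, 7 of 14 positive (adjusted p = 0.831), with the adhesion receptor gene CD44 at 1.19 and PROM1 at -1.46.

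No list of growth and survival genes passed. MYC target genes had 16 of 20 positive (adjusted p = 0.26), with LDHA at 0.31 (0.07 by its other probe) and PPAN at -0.63. Cell cycle genes had 19 of 25 positive (adjusted p = 0.113), with TYMS at 0.19 and BUB1B at 0.19. The BCL2 family had 9 of 16 positive (adjusted p = 0.695), led by BIK at 1.51, p53 target genes 12 of 18 (adjusted p = 0.176), with GADD45A at -1.10 (-0.71 without sensitive replicate 3) and TP53I3 at 1.12, and PI3K and mTOR genes 14 of 20 (adjusted p = 0.212), with the phosphatase gene INPP4B at 2.05 and the mTOR inhibitor gene DDIT4 at -0.69. INPP4B was at 0.65 at its smallest over all settings tried, and at -1.93 within slide 4. Cytokine receptor and JAK-STAT genes had 10 of 20 positive (adjusted p = 0.831), with BCL6 at -0.90, interferon response genes 8 of 20 (adjusted p = 0.831), with RSAD2 at 0.99 and XAF1 at -0.57 (-0.33 without sensitive replicate 2), and cholesterol synthesis genes 7 of 17 (adjusted p = 0.831), with STARD4 at -0.46 (-0.15 with slide as a block) and LSS at 0.31 (-0.07 without sensitive replicate 5), a gene whose other probes gave the opposite sign. Drug transporters and detoxification genes had 8 of 15 positive (adjusted p = 0.379), with GCLC at 0.57 (0.29 without sensitive replicate 3) and ABCC4 at 0.84 (0.47 without resistant replicate 10). In 6 lists, those of Hedgehog components, immature genes, oncogenes, the WNT pathway, JAK-STAT signalling and platelet markers, the median, the mean and the test did not share a sign.

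No list of markers of other cell types passed in either direction. These markers are human genes while the spleens were of mice, so the lists do not measure cells of the host directly. Natural killer and cytotoxic markers had 5 of 7 positive (adjusted p = 0.128), with NKG7 at 2.28 and CTSW at 2.08, each 0.0652 adjusted over the list alone. Myeloid markers had 7 of 10 positive (adjusted p = 0.382), with S100A8 at 1.83 and CD68 at 0.55. Erythroid markers had 3 of 10 positive (adjusted p = 0.831), with HEMGN at 1.17 and HBD at -0.86, B cell and plasma cell markers 2 of 9 (adjusted p = 0.831), with IGLL1 at 1.18 beside CR2, megakaryocyte and platelet markers 2 of 5 (adjusted p = 0.987), with GP1BB at 0.81 and ITGA2B at -0.40, and endothelial and stromal markers 1 of 9 (adjusted p = 0.438), with COL1A1 at -0.87 and CDH5 at -0.32. Several of these rested on 1 xenograft. S100A8 was at 0.45 and CD68 at 0.19 without sensitive replicate 4, HBD at -0.10 without sensitive replicate 3, IGLL1 at 0.66 and GP1BB at 0.21 without sensitive replicate 2, ITGA2B and CDH5 each at -0.14 without resistant replicate 8, and COL1A1 at -0.40 without resistant replicate 5.

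Over all tested genes together, sensitive and resistant xenografts were no farther apart than random groups of the same sizes. The group accounted for 6.07% of the variance (pseudo-F 0.905, exact one-sided permutation p = 0.534 over 8008 splits, and 0.472 over the 180 splits within slides). Mean correlations between arrays were 0.934 within the sensitive group, 0.919 within the resistant group and 0.926 between groups. The first principal component held 27.7% of the variance and did not separate the groups (exact p = 0.723).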

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

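The tests of the T cell receptor list and of the slide and scanning session, and the ranks of marker lists on 1 bright array, were chosen after the results they bear on were seen. A value was singled out when the gap between the highest or lowest xenograft of a group and its neighbour took an unusually large share of the group's whole range (Dixon's ratio, at its 95% critical value). Of 246 groups of values tested, 14 were singled out, where chance at about 1 in 20 gives 12.3, so the number as a whole was near that of chance.

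Resistant replicate 10 accounted for 6 of the 14. It was the highest of its group for GLI1, at 0.23 against -3.70 to -2.41 in the others (ratio 0.6701), and for HOXA7, at 1.79 against -7.22 to -3.34 (0.5696). It was the lowest for SMO, at -4.59 against 0.37 to 2.35 (0.7152), for TAL1 (0.6216), for ABCC4 (0.5904) and for the score of drug transporters and detoxification genes, at -0.733 (0.4898). Resistant replicate 8, the dimmest array, was highest for SUFU, at 0.84 against -2.08 to -1.46 (0.7892), and for FKBP4 (0.481), and lowest for IL7R (0.4664). Other resistant xenografts stood apart for ZNF618 (lowest, 0.4727) and IGLL1 (highest, 0.5238).

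Among sensitive xenografts, replicate 3 was highest for INPP4B, at -0.44 against -3.79 to -2.65 (0.6579). Sensitive replicate 5 was highest for LSS, at 3.46 against 0.91 to 1.40 (0.8083). Sensitive replicate 4 was highest for the score of myeloid markers, at 1.114 against -0.255 to 0.00906 (0.8072).

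The first pattern weighed was the lower level of NOTCH pathway genes in sensitive xenografts. Array brightness was argued against, since the list's median difference was -1.66 with brightness as a covariate and -1.70 without it. A lower share of leukaemic RNA in the sensitive samples was argued against too, because T cell receptor genes, which it would lower alike, had a median difference of 0.18. Chance could not be excluded: in 2410 of the 8008 splits of the 16 arrays, some list of the 31 had a standardized score difference as large as the real 2.30, with 3.45 the highest of the other splits. A difference in NOTCH activity between the groups, carried by 4 of the 6 sensitive xenografts, remains a hypothesis beside chance, with the share of leukaemic RNA undecided.

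The second pattern was the first principal component, whose correlation with array brightness was 0.592 in size (permutation p = 0.0197, Spearman 0.138). The scaling to the 75th percentile was argued against as its source, since the correlation was 0.762 after quantile normalization. The relation rested on the 2 dimmest arrays, both resistant: without them it was 0.0647. No biological explanation was tested.

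The third pattern was resistant replicate 5, with 89.6% of probes well above background where the next of the 16 had 76.8%. The other array of that slide and scanning session had 66.6%, so these alone did not raise the share on both. They cannot be excluded by 1 other array. Median background was 32 units on resistant replicate 5, 30 on that other array and 27 on the next highest array. RNA of other cell types stays open, since the marker lists are human genes and cells of the host are mouse cells. Of these lists, 0 of 3 had a median level above that of every other array. Stromal markers were higher on 1 other array and myeloid markers on 3, too near the top to exclude such RNA, while erythroid markers were higher on 16. Of 6247 probes above background on none of the other 15 labelled arrays, 61.3% were above it here, where its total alone requires 29.84%. A signal raised over dim probes as a whole may therefore be part of the pattern, and its source was not tested.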

How the results depend on the processing

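Leaving out the dimmest arrays, using brightness as a covariate and testing named genes only were chosen after the data were seen. All alternatives set before were run. No paired analysis was possible because nothing in the labels pairs a sensitive with a resistant xenograft.

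Under every alternative other than leaving out a xenograft, limma gave 0 genes past an adjusted p of 0.05, against 767 at an unadjusted p under 0.05 in the reported fit, and 0 probes when each was tested alone, with 931 at an unadjusted p under 0.05. Leaving out 1 xenograft gave 0 to 1 genes. The test of distance between groups stayed short of the threshold under every alternative tried. On leaving out 1 xenograft its pseudo-F ran from 0.729 to 1.04, with exact permutation p from 0.355 to 0.806. The highest pseudo-F over all settings was 1.22.

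The number of lists called, 6 as reported, was 3 with quantile normalization, 10 with no filter, 0 with an estimated correlation and 0 with fry, which asks a different question. It ran from 3 (without resistant replicate 10) to 8 on leaving out 1 xenograft. The estimated correlations, 0.203 for the NOTCH list against the preset 0.01, widen the test's own spread. The NOTCH list kept its sign in all settings, with medians from -2.42 to -0.47, and so did its score. None of the 6 called lists changed the sign of its median in any setting tried, while many of the other lists did. Within single slides signs did turn: the cortical thymocyte median was 0.45 within slide 1, and that of glycolysis and hypoxia was -0.12 within slide 2.

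With median centring, which raises all genes, the medians were 0.022 for Hedgehog components, 0.093 for glucocorticoid-induced genes, 0.046 for the glucocorticoid receptor complex, 0.13 for T-ALL oncogenes, 0.033 for T lineage factors, 0.097 for the WNT pathway, 0.046 for interferon response, 0.066 for cholesterol synthesis and 0.034 for platelet markers. With slide as a fixed block they were 0.16 for T-ALL oncogenes, 0.11 for interferon response, 0.23 for cholesterol synthesis, which was then called, and -0.17 for myeloid markers. With brightness as a covariate they were -0.045 for GLI targets, -0.091 for immature genes and -0.015 for JAK-STAT signalling, and with normexp and quantile normalization -0.0025 for GLI targets and -0.0031 for MYC targets. The strict filter gave 0.13 for B cell, -0.030 for myeloid and 0.35 for platelet markers. Without the 2 dimmest arrays the medians were 0.17 for glucocorticoid-induced genes, 0.066 for T lineage factors, and 0.20, 0.048 and 0.16 for erythroid, platelet and stromal markers. Without those and the array marked for evaluation they were 0.13 for Hedgehog components, 0.20 for glucocorticoid-induced genes, -0.047 for MYC targets, 0.023 for T lineage factors, and 0.25, 0.41 and 0.17 for the same 3 kinds of marker. Beyond median centring the cause was not tested.

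On leaving out each xenograft in turn, medians crossed 0 for the BCL2 family (-0.044 to 0.21), GLI targets (-0.078 to 0.15), MYC targets (-0.0031 to 0.17), T lineage factors (-0.16 to 0.051), T-ALL oncogenes (-0.15 to 0.18), cholesterol synthesis (-0.27 to 0.073), JAK-STAT signalling (-0.046 to 0.14), drug transporters (-0.060 to 0.19), stromal markers (-0.31 to 0.067), erythroid markers (-0.27 to 0.023), glucocorticoid-induced genes (-0.22 to 0.074), immature genes (-0.34 to 0.35), interferon response (-0.20 to 0.038) and platelet markers (-0.21 to 0.063).

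Among genes whose reported differences were near 0, GLI2 was 0.048 with quantile normalization. SUFU was 0.051 with the mean of all probes, 0.17 with array weights and 0.18 without the dimmest arrays, with or without the array marked for evaluation. NR3C1 was 0.13 with median centring, 0.045 with array weights and 0.014 with brightness as a covariate. LSS was -0.19 with the mean of all probes, and ITGA2B was 0.043 and 0.11, and CDH5 0.055, without the dimmest arrays, the last 2 values also without the array marked for evaluation. Resistant replicate 8, the dimmest, held the outlying SUFU value. For the others the cause was not tested.

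The Hedgehog score difference, -0.0211 as reported, was 0.0742 with quantile normalization, 0.11 with median centring, 0.136 with the strict filter, 0.018 with the mean of all probes, 0.0312 from log2 values, 0.105 without the 2 dimmest arrays and 0.151 without the 3 arrays in doubt. The GLI target score difference was -0.00264 with no filter and 0.347 with the strict filter (exact p = 0.0496). The cause was not tested.

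On leaving out each xenograft in turn, the ranges were -0.74 to 0.0062 for PTCH1, -0.13 to 0.82 for SMO, -0.32 to 0.14 for SUFU, -0.11 to 0.10 for NR3C1, -0.067 to 0.44 for LSS, -0.126 to 0.0362 for the Hedgehog score and 0.0832 to 0.605 for the correlation of GLI1 with NR3C1. The difference in percent of probes well above background ran from -2.54 to 0.979, and that in background brightness from -1.4 to 0.778. SMO went below 0, and the correlation fell to 0.0832, without resistant replicate 10, whose values of GLI1 and SMO stood apart.

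Counting each pair of a named gene and another setting, 1191 kept their direction and side of the threshold and 12 changed sign. No named gene passed in the reported fit, so keeping its side meant only that a gene stayed uncalled. On leaving out 1 xenograft, 1396 kept both, 11 changed sign and 1 passed. For lists the numbers were 278 kept, 14 newly past, 28 no longer past and 33 with the sign of the median changed, and 421, 16, 17 and 42 on leaving out 1 xenograft. Signal over background limits genes that were dark on several arrays, among them GLI3, ZFPM2, ZNF114, CST7, RAVER2, ZNF618, LINC01777, HES1, HES5, DTX1, HOXA7, PROM1, S100A8 and COL1A1.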

Other observations

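The relation of GLI1 to the NOTCH score, and its values within groups, were chosen for testing after the results were seen. The 4 xenografts with no stated response are given as lowest, median and highest log2 level. GLI1 stood at -4.01, -3.09 and -2.05, GLI2 at -4.88, -3.93 and -3.38, SMO at 0.37, 1.23 and 2.13, and NR3C1 at 2.86, 3.59 and 3.97. HES4 ranged from -1.39 to 8.38 and NOTCH3 from -3.96 to 4.45, which spans most of the range of the other 16. SEPTIN11 ranged from -3.28 to 2.41, RAVER2 from -3.90 to -1.80 and METRN from 2.97 to 5.55.

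Splits of the 16 arrays into 6 and 10 were counted, 100 in all with the real one included. For genes past an adjusted p of 0.05 the real count was 0, which all 100 must reach, so that comparison says nothing about chance, and the highest of the others was 1. For genes at an unadjusted p under 0.05, 62 of 100 splits gave as many as the real 767, with 4255 the highest, several times the real count. Such a split may point to a structure of the samples, which was not tested. For lists past an adjusted p of 0.05, 42 of 100 gave at least the real 6, with 14 the highest. Chance could not be excluded for either of these counts.

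A hypothesis that xenografts with more GLI1 have less NOTCH activity was tested on the same arrays. Across 16 xenografts, Pearson r of GLI1 and the NOTCH score was -0.383 (permutation p = 0.144) and Spearman rho was -0.394 (permutation p = 0.134, or 0.268 after adjustment over 2 relations), so the relation was not held up. Without the 2 xenografts farthest in GLI1, r was -0.725. It was -0.762 within slide 1 and -0.217 within slide 2. Within the 6 sensitive xenografts r was -0.927 (exact permutation p = 0.0125) and rho was -0.943 (exact permutation p = 0.0167), or 0.05 and 0.0667 adjusted over 4 relations within groups. Without the 2 farthest, r there was -0.864. Within the 10 resistant ones r was 0.362 (permutation p = 0.352), and -0.73 without the 2 farthest, so its sign rests on those. Whether the groups differ in this was not tested. With each group's mean removed r was -0.198, just above the bound of -0.2 set beforehand. Given the relation within the sensitive group and the weight of 2 resistant xenografts, whether the difference between groups alone accounts for the pooled r stays open.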
